A study of Mus musculus with 2 samples.

How the data were processed

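Primary macrophages were grown from the bone marrow of C57BL/6 mice, transfected with an antisense oligonucleotide (ASO) and treated with lipopolysaccharide (LPS), the bacterial cell wall component that activates macrophages through TLR4. The samples were 1 library from cells given a control ASO (Control-ASO) and 1 library from cells given an ASO named for Acly (AclyE14-ASO). Total RNA was isolated on columns and turned into mRNA libraries for Illumina sequencing, per the labels' protocols, which name both a stranded total RNA kit and a mRNA capture kit. The dose and duration of the LPS treatment are not given in the sources used here.

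The deposited table holds raw gene counts and FPKM values for 34745 Ensembl gene identifiers in both libraries, per the file headers. HISAT2, StringTie 1.3.0, edgeR and the mm10 build are named in the submitters' processing notes, which assign them no role. Whether counting used the strand, and how reads shared by several genes were assigned, is not given in the sources used here. The relation between the deposited FPKM values and the deposited counts was checked: among genes with more than 20 counts in both libraries, FPKM per count differed between the libraries by a factor of 1.1148 to 1.1149, and the ratio of the count totals was 1.115. The FPKM values were therefore scaled by the authors to the summed gene counts of each library and to 1 fixed length per gene, with no further scaling between the libraries. Symbols were matched by gene identifier to GENCODE M21 (GRCm38, the assembly also called mm10) for 34267 of the identifiers. The 478 identifiers without a symbol held 0.175% of the Control-ASO counts and 0.136% of the AclyE14-ASO counts and stayed in the totals.

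Each group had 1 library, so no test across genes was run, no p-value is given and no difference has a replicate check. The main value was the log2 ratio of FPKM + 1, AclyE14-ASO over Control-ASO, for genes with a mean of at least 1 FPKM over the 2 libraries. The pseudocount understates the change of low genes. Ratios of counts per library total, without a pseudocount, are given with exact (Clopper-Pearson) 95% intervals from the conditional binomial distribution. These intervals cover counting error only, and sequencing reads without molecular identifiers are not independent molecules. A gene was called higher or lower by size, at 2-fold or more among all genes and at 1.5-fold or more among members of a gene list.

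The 31 gene lists, the size thresholds and the rule for named genes were fixed before the data were examined. The rule took Acly, the 10 genes with the largest and the 10 with the smallest log2 ratio among the 4725 genes with a symbol and a mean of at least 5 FPKM, and, per list, up to 2 members at each end and the most abundant member (not all of these are reported here). Other genes were named after their values were seen, among them Il1b, Il6, Ptgs2, Osm and Il12b. Each list's median was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, which describes these libraries and tests no difference between the treatments. About 1.55 of 31 lists would lie outside the central 95% of random lists if the genes within each list varied independently. Genes within a list can vary together between single cultures, which would put more lists outside, and lists that share genes are not independent. The number of lists outside is therefore not judged against 1.55.

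The alternatives were pseudocounts of 0.1 and 5, log2 ratios centred on the median gene, FPKM rescaled by the trimmed mean of M values (TMM), CPM (counts scaled to library totals) with TMM factors, no filter or a mean of at least 5 FPKM, and thresholds of 1.5-fold and 4-fold. Centring used the median over genes with a mean of at least 5 FPKM. TMM factors came from edgeR 4.0.16 in R 4.3.3, and all else was computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Removal of the trends of the log2 ratio on gene length and transcript GC content, summing of reads over overlapping genes, and a count without stromal genes were chosen after seeing the data. The calculations were tested on simulated counts for this comparison, with genes drawn from the 8658 expressed genes raised or lowered 3-fold, and 8629 genes passed the expression limit in that simulation. Among genes of 5 FPKM or more, 100% of those raised 3-fold and 98.3% of those lowered 3-fold were called, and over all genes changed in the simulation the shares were 94% and 71%. In a simulated pair without any change, in which 8668 genes passed the expression limit, counting noise put 0 genes at 2-fold higher and 1 gene at 2-fold lower.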

Results

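RNA sequencing compared LPS-treated mouse bone marrow-derived macrophages transfected with the AclyE14-ASO, the oligonucleotide named for Acly, with cells transfected with a control ASO. Each condition was 1 library. The Control-ASO library held 14215397 gene counts over 14445 genes and the AclyE14-ASO library 12751076 counts over 14653 genes. A mean of at least 1 FPKM was reached by 8658 genes. All differences below lie between these 2 libraries, have no replicate check, and may include culture-to-culture variation. Values are FPKM, log2 ratios are of FPKM + 1, and intervals are exact 95% intervals for counting error. Genes were called higher or lower on FPKM + 1, so a low gene can miss a limit that its FPKM or counts pass.

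Acly, which encodes ATP-citrate lyase, the enzyme that makes cytosolic acetyl-CoA from citrate, was lower in the AclyE14-ASO library. Its level (ENSMUSG00000020917, chromosome 11, 100476353 to 100528000, minus strand, GRCm38) was 13.3 FPKM from 1549 counts with the control ASO and 7.35 FPKM from 768 counts with the AclyE14-ASO. Relative to the library totals this was 44.7% lower, with a counting interval of 39.7% to 49.4%, and the log2 ratio was -0.78. Only 3.46% of expressed genes had a lower log2 ratio. The labels do not spell out E14. In the GENCODE M21 annotation, exon 14 of the transcripts Acly-203 and Acly-202 spans 30 nt at 100503160 to 100503189. The transcript Acly-201 passes from exon 13, which ends at 100504203 on this strand, directly to the exon at 100498621 to 100498762. The gene-level values do not resolve the use of this exon.

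Across the transcriptome, 275 genes were higher by 2-fold or more in the AclyE14-ASO library and 134 were lower, while 84.5% of expressed genes lay within 1.5-fold. The median expressed gene had a log2 ratio of -0.13. Centring the ratios on the median over genes with a mean of at least 5 FPKM, also -0.13, shifts every ratio by 0.13 and gives 348 higher and 91 lower genes. The share of higher genes then moves from 67.2% to 79.3%. At 1.5-fold, without centring, the balance turned, with 609 higher and 734 lower genes. Among the 458 genes with a mean of 100 FPKM or more, 16 were higher and 9 lower by 2-fold.

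The genes with the largest ratios included secreted immune mediators and mesenchymal genes. The cytokine gene Il1a was at 846 and 4383 FPKM, a count ratio of 5.18 (interval 5.11 to 5.25). Csf2 and Csf3, the genes for the myeloid growth factors GM-CSF and G-CSF, had 5 against 100 counts and 68 against 445 counts, ratios of 22.3 (9.24 to 70.2) and 7.30 (5.64 to 9.56). Col1a1, a fibrillar collagen chain, was at 2.99 and 20.2 FPKM, and Tagln, an actin-binding protein of smooth muscle and fibroblasts, at 12.6 and 71.9 FPKM. Aebp1 was 12.4 times as high by counts (9.64 to 16.3), and Timp1, an inhibitor of matrix metalloproteinases, 8.06 times (7.08 to 9.20). Among genes with a mean of at least 5 FPKM, S100a4 had the largest log2 ratio, 3.16, with 5.31 against 55.4 FPKM, and the metallothionein Mt2 followed at 3.02.

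Among genes at the other end, the class Ib histocompatibility gene H2-M2 stood out by its abundance. It was at 394 FPKM with the control ASO and 29.5 FPKM with the AclyE14-ASO, a ratio of 0.0748 (0.0697 to 0.0801). Dio2, which activates thyroid hormone, was at 41.3 and 3.22 FPKM, a ratio of 0.0781 (0.0682 to 0.0891). Pepd, a dipeptidase, the transcriptional repressor Bhlhe41, the formyl peptide receptor Fpr1, the MAP kinase phosphatase Dusp4 and the chemokine receptor Cxcr4 had log2 ratios of -2.13, -2.11, -2.05, -2.04 and -2.03. The lowest ratios belonged to Gm26712, with 118 against 1 counts, Gm49368, with 1834 against 6, and Gm21981, with 731 against 0. Each of these overlaps another expressed gene on its own strand (Pyurf, Itgam and Tomm6), so their values are uncertain. The summed counts of Gm26712 and Pyurf had a ratio of 0.929 (0.793 to 1.09), an interval that includes no difference.

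**Figure D1:**
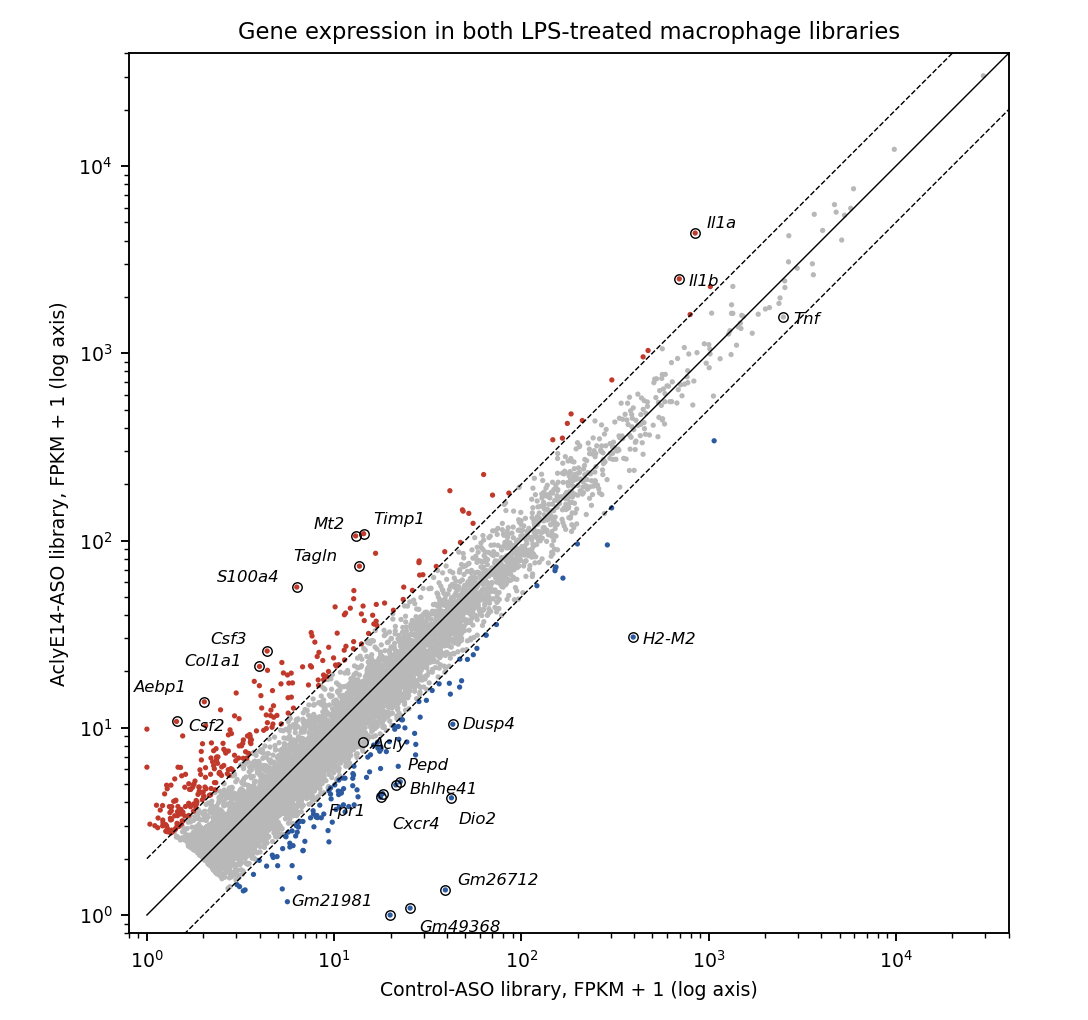
Expression of the 8658 expressed genes in the Control-ASO library (x axis) and the AclyE14-ASO library (y axis), as FPKM + 1 on log axes, with 1 point per gene. Red points were higher and blue points lower by 2-fold or more (dashed lines), circles mark Acly, the genes at the extremes that are described in the text, Il1b and Tnf, and Il1a at 846 and 4383 FPKM lies far above the diagonal while H2-M2 at 394 and 29.5 FPKM lies far below it.

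Inflammatory cytokines and enzymes were higher as a group, but not uniformly. Of 30 members, 15 were higher by 1.5-fold or more, 1 was lower and 14 lay between. The median log2 ratio was 0.55, above all 10000 random lists. Besides Il1a, Csf2 and Csf3, the genes Il1b (696 and 2495 FPKM, ratio 3.59, 3.53 to 3.64), Osm (4.63 and 18.1 FPKM), Il12b (3.76 and 10.4 FPKM), Ptgs2, the inducible cyclooxygenase (246 and 434 FPKM), and Il6 (35.3 and 58.5 FPKM) were higher. Tnf was lower, at 2504 and 1560 FPKM (ratio 0.623, 0.617 to 0.629). Acod1, which makes itaconate, was at 1438 and 1384 FPKM, and the inducible nitric oxide synthase Nos2 at 22.2 and 31.4 FPKM. Fibroblast and stromal markers, with a list median of 1.73, were higher in the same library.

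Chemokine genes had a smaller shift. Of 20 measured members, 4 were higher by 1.5-fold and 1 was lower, and the median of 0.31 lay above 99.9% of random lists. Of the higher members 3 were among the 5 at 1 to 5 FPKM and 1 among the 15 at 5 FPKM or more, where the median was 0.22. The stromal list's median was 1.73 in the same comparison. The abundant Ccl3 (5733 and 5947 FPKM), Ccl2 (586 and 771 FPKM) and Cxcl10 (865 and 1007 FPKM) lay within 1.5-fold. Ccl12 (8.13 and 17.8 FPKM) and Ccl17, with 2 and 13 counts, were higher, and Ccl9 was lower (302 and 148 FPKM). Ccl22 was at 7.68 and 6.49 FPKM.

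Components of the LPS receptor and of NF-kB signalling moved in both directions. Cd14, the LPS co-receptor, was at 1020 and 2270 FPKM (ratio 2.23, 2.19 to 2.26), while Tlr4 itself was at 4.96 and 0.835 FPKM (ratio 0.168, 0.129 to 0.216). Of the 18 measured TLR4 signalling genes, 1 was higher and 3 lower, with a median of -0.27 at percentile 7.60 of random lists. Ticam2 was lower (12.3 and 6.26 FPKM). It shares its locus with Tmed7, which was lower too (1622 and 1073 counts) and so did not gain the reads missing from Ticam2. The summed counts of both had a ratio of 0.669 (0.625 to 0.715), an interval that spans the 1.5-fold limit. Ly96, which encodes MD-2, had 221 and 243 counts. Of 26 NF-kB pathway and feedback genes, 3 were higher and 1 lower, with a median of 0.08 at percentile 96.4. Vcam1 (4.90 and 18.6 FPKM) and Bcl3 (6.29 and 15.9 FPKM) were higher, and Tnfaip3, the gene for the inhibitor A20, was lower (77.3 and 38.8 FPKM). Marcksl1, the most abundant member, was at 514 and 727 FPKM and Relb at 18.9 and 14.6 FPKM.

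Interferon-stimulated genes differed little between the libraries. Of 49 measured members, 46 lay within 1.5-fold, 1 was higher and 2 were lower. The median log2 ratio was -0.10, at percentile 14.2 of random lists, and turned to 0.03 when centred on the median gene. Rsad2, which encodes viperin, was higher (1345 and 2273 FPKM), Irf9 (24.0 and 13.9 FPKM) and Ifi44 (15.9 and 9.16 FPKM) were lower, and Isg15 was at 4059 and 4529 FPKM. Ifnb1 itself was at 172 and 155 FPKM. Irf9 shares its locus with Rnf31, and the summed counts of both genes had a ratio of 0.742 (0.708 to 0.776), within 1.5-fold. Rnf31 alone had 1669 and 1539 counts, so it did not gain the reads missing from Irf9 (2927 and 1518 counts). The sum therefore does not set aside the lower level of Irf9.

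Anti-inflammatory and alternative-activation genes had a median of 0.44, above all 10000 random lists. Of 23 measured members 10 were higher, 3 lower and 10 between. Stromal markers (median 1.73) were higher in the same library, and the cell cycle list had a median of 0.79, but -0.07 over its members at 5 FPKM or more. Il10 was at 27.4 and 76.8 FPKM (ratio 2.80, 2.52 to 3.11), and Clec7a, the beta-glucan receptor dectin-1, at 175 and 421 FPKM. Tgfbi (7.14 and 2.31 FPKM) and Socs1, a feedback inhibitor of cytokine signalling (50.5 and 22.2 FPKM), were lower.

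Pathways fed by cytosolic acetyl-CoA include cholesterol and fatty acid synthesis. Of 19 measured cholesterol synthesis genes 5 were lower and 1 higher, and the median of -0.36 lay above only 0.56% of random lists. Pmvk was lower (2.99 and 1.45 FPKM), and Srebf2, the main transcriptional regulator of the pathway, was at 25.2 and 17.5 FPKM and Cyp51 at 4.53 and 5.38 FPKM. Of 15 measured fatty acid synthesis genes 5 were higher and 0 lower, with a median of 0.18 above 99.6% of random lists. Only 12 of the 26 listed genes reached 1 FPKM in the control library. The higher genes Scd2, Fasn and Fads2 did not, and were measured only through their level in the AclyE14-ASO library. Only 1 of the 8 members at 5 FPKM or more was higher, against 4 of the 7 at 1 to 5 FPKM, and the median over those 8 was 0.09. Stromal markers, with a median of 1.73, were higher in the same library. The higher members were Elovl5 (1.34 and 6.73 FPKM), Fads2, with 9 and 36 counts, Fads1, Scd2 and Fasn, all at low levels, while Elovl1 was at 15.4 and 10.5 FPKM, Acsl1 at 11.3 and 8.98 FPKM and Insig1 at 27.0 and 33.1 FPKM. The other 11 members lay below a mean of 1 FPKM. Of 18 LXR target and lipid handling genes 2 were higher and 3 lower (median -0.27, percentile 3.82). Lipa, lysosomal acid lipase (61.8 and 224 FPKM), and Apoe (446 and 956 FPKM) were higher. Fabp4 (90.8 and 47.3 FPKM) and the lipid droplet gene Plin2 (399 and 236 FPKM) were lower. Npc2 was at 1013 and 1053 FPKM.

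Energy metabolism and acetylation genes stayed mostly within 1.5-fold. Of 28 TCA cycle and citrate supply genes, 4 were lower and 1 was higher (median -0.23, percentile 11.8). Aco1 was lower (10.9 and 5.87 FPKM), Sdhb was higher (19.6 and 37.0 FPKM), and Sdhd, the most abundant, was at 103 and 82.6 FPKM. Among 21 glycolysis genes 2 were higher and 1 lower (median 0.02, percentile 88.6), with Pkm at 388 and 404 FPKM, Aldoc at 1.75 and 3.75 FPKM and Pfkl at 8.27 and 5.13 FPKM. Among 28 nuclear-encoded oxidative phosphorylation genes 1 was higher, Cox6c (14.5 and 22.5 FPKM), and 0 were lower. That median, -0.06 at percentile 72.2, changed sign under centring and TMM. Of 19 measured members of the histone acetyltransferase list only Naa50 was lower on FPKM + 1 (12.5 and 7.75 FPKM; median -0.24, percentile 12.4), with Kat2a at 2.48 and 3.49 FPKM. By counts, without a pseudocount, Brd1 was lower beyond 1.5-fold too (ratio 0.641). Of 12 deacetylases and acetyl-lysine readers 0 passed 1.5-fold on FPKM + 1 (median -0.23, percentile 24.0, and -0.11 over members at 5 FPKM or more), with Brd2 at 50.1 and 40.5 FPKM. By counts Hdac5, Sirt1 and Brd9 (11.4 and 7.56 FPKM) were lower beyond 1.5-fold, with ratios of 0.613, 0.660 and 0.663. The counting intervals of Brd1 and of these genes all spanned the 1.5-fold limit. Of 35 splicing regulators only Srsf2 was lower on FPKM + 1 (20.6 and 10.6 FPKM) and 0 were higher (median -0.19, percentile 23.1, and -0.09 over members at 5 FPKM or more), with U2af2 at 66.9 and 65.0 FPKM and Tra2a at 16.3 and 21.4 FPKM. By counts Srsf11, Celf1 and Tial1 were lower beyond 1.5-fold too, with ratios of 0.600, 0.610 and 0.624.

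Stress lists were mixed. Of 25 NRF2 and oxidative stress genes 4 were higher and 7 lower, and the median of -0.20 (percentile 7.78) and the mean of 0.06 differed in sign. Mt2, Gpx1 (40.5 and 183 FPKM), Nqo1 (log2 ratio 2.09) and Mt1 were higher. Gclc (5.45 and 1.95 FPKM), Pgd (37.8 and 20.3 FPKM), Hmox1, G6pdx, Gsr, Taldo1 and Txnrd1 were lower, several of them enzymes of glutathione and NADPH supply. Fth1, the most abundant transcript of the table, was at 29290 and 30338 FPKM. Of 25 unfolded protein and integrated stress response genes 4 were lower, among them Chac1 (704 and 313 counts), Dnajb9 (24.9 and 15.6 FPKM) and Atf4 (445 and 288 FPKM), and Hspa5 was higher (78.1 and 122 FPKM). That median of -0.01 (percentile 87.5) turned positive under centring and TMM. Of 20 heat shock and immediate-early genes 4 were higher, led by Ier2 (6.89 and 27.7 FPKM) and Hspb1 (1.61 and 6.55 FPKM), and Dnajb1 was lower (516 and 281 counts; median 0.08, percentile 96.5). Of 24 p53 target and cell death genes 2 were higher, Phlda3 (1.72 and 4.97 FPKM) and Bcl2l1 (0.904 and 2.54 FPKM), and Pmaip1 was lower (6.01 and 3.65 FPKM; median 0.03, percentile 92.3, and -0.01 over members with a mean of at least 5 FPKM), while Bcl2a1b was at 1298 and 1318 FPKM.

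Most lysosome and macrophage identity genes lay within 1.5-fold. Of 36 lysosome and phagocytosis genes 5 were higher, 4 lower and 27 between. The median of 0.16 lay above 99.5% of random lists, and the mean was -0.01. Ctsk, the cathepsin best known from osteoclasts, was lower (1069 and 340 FPKM, ratio 0.318, 0.309 to 0.327), as was the leukocyte integrin Itgb2 (287 and 93.7 FPKM). Fcgr1 (34.7 and 68.2 FPKM) and Gusb (45.3 and 85.7 FPKM) were higher, and Ctss was at 4696 and 6221 FPKM. Of 23 macrophage markers 6 were higher, 4 lower and 13 between (median 0.16, percentile 98.5, and 0.26 over members at 5 FPKM or more). Lyz2 was at 9798 and 12276 FPKM, Cd68 was lower (1059 and 590 FPKM), and so was the myeloid transcription factor Cebpa (6.76 and 2.46 FPKM). Itgam was listed at 9.12 and 43.2 FPKM, but it shares its locus with Gm49368, and the summed counts of both genes differed by a ratio of 1.60 (1.53 to 1.68). Of 22 antigen presentation genes 1 was higher, H2-DMa (2.20 and 7.01 FPKM), and 2 were lower, H2-Q7 (63.8 and 30.2 FPKM) and H2-Q4 (184 and 111 FPKM). These class I genes are near copies of others, so reads may be split among them. B2m was at 5935 and 7558 FPKM, and the list's median of -0.07 (percentile 54.4) changed sign under centring and TMM.

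Markers of other cell types were examined as well. The stromal list (fibroblast, stromal and endothelial markers) had the highest median of the lists with 5 or more measured members, at 1.73, above all 10000 random lists. Of its 12 measured members 9 were higher by 2-fold or more, among them Col1a1, Tagln, Sparc (10.3 and 39.1 FPKM), Acta2 (13.3 and 43.7 FPKM) and Dcn (7.29 and 24.3 FPKM). Fabp4 and Kdr (11.1 and 5.49 FPKM) were lower, and 9 of the 20 listed genes already reached 1 FPKM in the control library. The cell cycle list moved with it. Of its 24 measured genes 15 were higher and 0 lower (median 0.79, above all 10000 random lists), including Ccnd1 with 17 and 200 counts, Cdc20 with 22 and 118 counts, and Mki67 at 1.98 and 4.15 FPKM. Only 15 of the 44 listed genes reached 1 FPKM in the control library, so some members were measured only through their level in the AclyE14-ASO library. Of the higher genes 13 had means under 5 FPKM, and over the 7 members at 5 FPKM or more the median was -0.07. Pcna, the most abundant, was at 69.2 and 64.9 FPKM, and Bub1b at 11.7 and 8.47 FPKM.

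Blood lineage markers were scarce. Only 4 of 20 neutrophil markers reached a mean of 1 FPKM, led by S100a8 (19.7 and 41.4 FPKM), with Csf3r at 4.17 and 6.58 FPKM and a median of 0.37 at percentile 98.0. Only 1 of 22 lymphocyte markers, Lck (3.23 and 5.26 FPKM; log2 ratio 0.56, percentile 91.4), and 1 of 20 erythroid, megakaryocyte and mast cell markers, Pf4 (1.29 and 4.10 FPKM; log2 ratio 1.15, percentile 97.7), did so. Of 5 measured dendritic cell markers the actin-bundling gene Fscn1 was higher (2.74 and 16.7 FPKM; list median 0.14, percentile 86.1), with the interferon-induced Bst2 at 743 and 683 FPKM.

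Transcripts that track RNA composition also differed. Of 12 mitochondrially encoded transcripts 11 lay within 1.5-fold, with a median of -0.35 above only 0.23% of random lists, and mt-Co1 was at 5131 and 4023 FPKM. The exception was mt-Nd6, with 27 and 60 counts. All 28 measured cytosolic ribosomal protein genes lay within 1.5-fold, with a median of 0.21 above 99.8% of random lists and Rplp1 at 1324 and 1814 FPKM. Of 4 measured replication-dependent histone genes 1 was higher, Hist2h2aa1, with 0 and 66 counts (median 0.33, percentile 97.0). It overlaps Gm20634, which had 10 and 140 counts, and the summed counts had a ratio of 22.97 (12.2 to 48.6). Hist1h2bc was at 81.5 and 77.4 FPKM. In all, 11 of the 31 lists lay above and 2 below the central 95% of random lists. The neutrophil list and the erythroid, megakaryocyte and mast cell list were among the former, on 4 and 1 genes. Members of a list can vary together between single cultures, so these numbers were not judged against the number expected for independent genes.

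**Figure D2:**
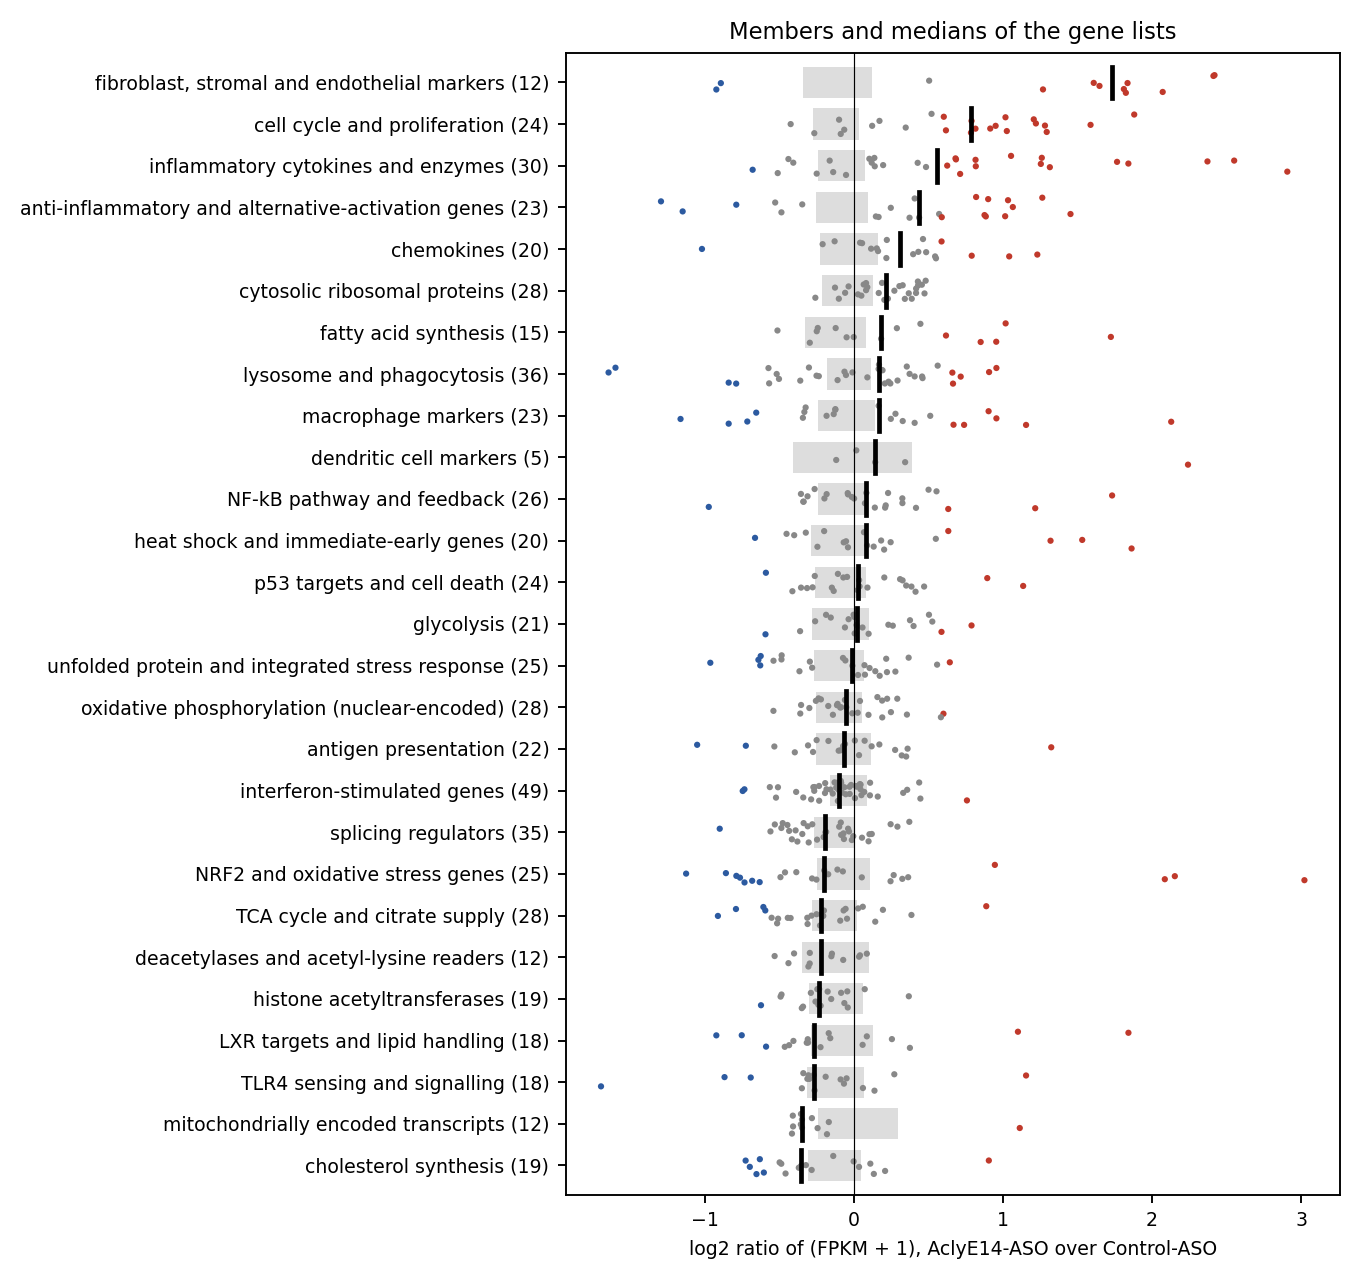
Log2 ratio of FPKM + 1, AclyE14-ASO over Control-ASO (x axis), for the members of the 27 gene lists with at least 5 measured members (y axis, number measured in brackets). Points are genes (red higher and blue lower by 1.5-fold or more), black bars are list medians and grey bands the central 95% of medians of 10000 random lists matched on expression; the stromal list, with a median of 1.73, and the cell cycle list, at 0.79, lie farthest to the right of their bands.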

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

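The counts of 275 higher and 134 lower genes varied with the settings. With pseudocount 5 there were 82 higher and 42 lower genes, with pseudocount 0.1 there were 264 lower, with CPM with TMM 785 higher and 220 lower, with a mean of at least 5 FPKM 127 higher, at 1.5-fold 609 higher and 734 lower, and at 4-fold 28 higher and 12 lower. CPM changes the length scaling, the library scaling and the weight of the pseudocount together. Leaving out both stromal lists gave 247 higher and 134 lower; this alternative and the removal of length and GC trends were chosen after seeing the data. The median log2 ratio of all expressed genes, -0.13, was -0.15 with pseudocount 0.1, -0.0718 with pseudocount 5, 0.00216 when centred, -0.0453 with TMM-rescaled FPKM, -0.0251 with CPM and -0.0309 without a filter. Acly kept its direction in every alternative run, which none of these small shifts could have changed. Its log2 ratio of -0.78 moved to -0.57 with pseudocount 5 and to -0.65 when centred. These values hold a pseudocount and its counting interval does not, so they are not judged against that interval. The cell cycle median of 0.79 reversed to -0.0673 with a mean of at least 5 FPKM, which leaves 7 of 24 genes, and was 1.13 with CPM. The interferon-stimulated median, -0.10, became 0.0274 when centred, -0.00284 with TMM-rescaled FPKM, -0.00177 with CPM and 0.0379 with length and GC trends removed. The splicing regulators, at -0.19, moved to -0.0648 when centred, -0.0271 with CPM and -0.0642 with the trends removed. The lysosome median of 0.16 moved to 0.29 when centred and 0.32 with the trends removed, and the stromal median of 1.73 to 2.07 with pseudocount 0.1. Whether a list median moved was judged against its binomial 95% interval over members. Of the other genes compared under every scaling and pseudocount, 75 differed by 2-fold or more and 0 of these changed sign. This was fixed in advance, since a pseudocount keeps the sign and the scalings shift ratios by far less than 2-fold. The sign changed for 9 genes within 1.5-fold, among them Pcna, Acod1 and Actb. The cause of the moves was not tested beyond what each alternative changes by construction. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. Depth limits the genes with few reads, such as Csf2 with 5 control counts.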

Other observations

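The genes of this paragraph were picked after their values were seen, and all tests below except that of the second mesenchymal list were chosen after the results were seen. Outside the lists, Cst3, cystatin C, was higher in the AclyE14-ASO library (303 and 719 FPKM), as were Acp5, tartrate-resistant acid phosphatase (146 and 344 FPKM), Wfdc17 (183 and 473 FPKM), Serpinb2 (51.4 and 139 FPKM) and Lgals1, galectin-1 (795 and 1609 FPKM). Hilpda, an inhibitor of lipolysis on lipid droplets, was at 165 and 351 FPKM. The complement receptor C3ar1 (198 and 94.9 FPKM), the inhibitory receptor Cd300a (21.2 and 7.68 FPKM), Gpr141 (10.2 and 2.88 FPKM), the repressor Bcl6 (10.4 and 2.56 FPKM) and the kinase Rps6ka2 (166 and 62.0 FPKM) were lower. Lgals1 and Cst3 are also expressed by stromal cells, whose markers were higher in the same library.

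Stromal and matrix genes were higher in the AclyE14-ASO library, and a candidate source is a larger share of stromal-type cells in that culture. A second list of 51 mesenchymal and matrix genes, fixed before its values were seen, had a median log2 ratio of 1.02 over 35 measured members, of which 24 were higher by 1.5-fold, 0 were lower and 23 of the 51 reached 1 FPKM in the control library; it lay above all 10000 random lists, and its median over the 13 members at 5 FPKM or more was 0.53. Its most abundant gene, Vim, which macrophages also express, was at 306 and 291 FPKM, and Tagln, with the largest gain of either list, was at 12.6 and 71.9 FPKM. Gene length and GC content are argued against, since the median log2 ratios of 10 bins of genes by length or by GC content differed by at most 0.11, against the first list's median of 1.73. Expression of these genes by macrophages under the ASO was not tested, and with 1 library per group it cannot be told apart from a difference between single cultures.

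Il1a and Il1b were far higher while Tnf was lower and the interferon-stimulated genes differed little. Il1a and Il1b together gained 5336 FPKM, 14.7 times the 362 FPKM gained in sum by members of the 2 stromal lists. That sum took all members with any gain, whether or not they reached 1.5-fold, and the largest single gain was 59.3 FPKM. The gain of listed markers does not limit how much of other transcripts such cells could add, so stromal-type cells stay open as a source. A scaling factor moves every gene alike and is argued against by the median of all expressed genes, -0.13, and length or GC bias by the same largest difference of 0.11 between bins. An effect of the ASO, stromal-type cells and a difference between single cultures remain open, and with 1 library per group the data cannot tell them apart. The hypothesis that the ASO shifts LPS-treated macrophages towards interleukin-1 output relative to Tnf may be worth replicate cultures.

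Of genes with at least 200 reads in the higher library, 4 were at least 20 times lower in the other, and 100% of these overlapped a same-strand gene with 50 or more reads, against 2.48% of 6819 other genes. At 2 of these loci the partners differed the other way, which argues against loss or gain of Gm49368 or Gm20716 alone, but by more than a move of all reads would give, so moved reads could be only a part: Itgam was at 4.74 (interval 4.41 to 5.10) against 2.96, with a summed ratio of 1.60, and Adnp and Dpm1 together at 0.405 (0.358 to 0.457) against 0.609, with a summed ratio of 0.796. At the other 2 loci a move of all reads to the partner is argued against. Srcap stayed at 1.03 (interval 0.930 to 1.14), where all reads of Gm42715 would have brought it to 1.25, and Tomm6 was at 0.676, where those of Gm21981 would have brought it to 2.46. The summed ratios there, 0.827 for Gm42715 and Srcap and 0.275 (interval 0.242 to 0.312) for Gm21981 and Tomm6, leave a lower level of Gm42715 and Gm21981 open.

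Some household genes with many processed copies were listed at low levels. Gapdh was at 13.1 and 13.2 FPKM and Ppia at 0.795 and 0.918 FPKM, against 377 and 364 FPKM for Actb. The processed pseudogene Tpt1-ps3 held 27020 and 36527 counts, more than the parent gene Tpt1 with 2557 and 3288.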
